A study of Homo sapiens with 15 samples.

How the data were processed

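RNA sequencing of 15 libraries labelled as MDA-MB231, a human triple-negative breast cancer cell line, was analysed. Per the labels' protocols, the cells were kept in DMEM and RNA was extracted with an RNeasy mini kit. A depletion dataset held 9 libraries, 3 each of the groups CTRL, SG1 and SG3, and an overexpression dataset held 6, 3 each of EV and KIF20A_OE. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says what SG1 and SG3 stand for beyond a depletion of KIF20A, or that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

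The depletion dataset was deposited by the authors as raw counts per gene, and the values were whole numbers with different totals per library. The overexpression dataset is called FPKM per the labels, but each deposited column summed to 1000000 and held whole multiples of a fixed step, so the values were fragments per 1000000 fragments (FPM), the fragment form of CPM, with no gene length in them. Dividing by the step gave whole fragments for 100% of values in each library, within a tolerance of 0.001 fragments. The planned design had assumed FPKM. Its test on the log2 scale suits FPM as well and was kept. Per the submitters' processing notes, the tools were Trim Galore 0.6.4, STAR 2.7.3a, featureCounts, Subread 1.6.3 and limma 3.50.3 with build hg38. Their roles, the annotation release, the strand setting and any filter are not given in the sources used here. Of the gene identifiers, 96.3% in the count table and 97.3% in the FPM table matched GENCODE 29 on GRCh38, which supplied coordinates. The FPM table listed 23792 genes, with no mitochondrially encoded gene and no gene under 7 fragments in total, against 60651 genes in the count table. How reads shared by paralogs, pseudogenes or overlapping genes were assigned is not given in the sources used here, so values of ribosomal protein, mitochondrial, keratin and HLA genes are uncertain to that extent.

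Library totals, with M for 1000000, were 40.9 to 51 M counts in the depletion dataset and 16 to 22.2 M recovered fragments in the overexpression dataset. A gene with no count had a floor of 3 counts, equal to 0.0588 to 0.0734 CPM per depletion library and 0.135 to 0.188 FPM per overexpression library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Among counts of 10 to 50 in the depletion dataset, 62.9 to 68% per library were even. The cause was not established, and halved counts were run as an alternative. Replicates of a group differed by more than sampling noise, with a chi-square of 11.65 to 131.5 per degree of freedom, so all libraries were used separately.

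The depletion counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default expression filter, in a single fit of the 9 libraries. It kept 16786 genes. Contrasts were SG1 against CTRL, SG3 against CTRL, SG1 against SG3, and the mean of SG1 and SG3 against CTRL. The overexpression values were tested with limma 3.58.1, with trend and robust moderation, on log2(FPM + 1) for the 15265 genes with a mean of at least 1 FPM. Fold changes on that scale understate the change of low genes, so genes without fragments in a group are given as a fold over the floor of 3 fragments per library, and other named genes as a ratio of pooled rates with an exact 95% interval. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The datasets were scaled separately and were not tested against each other. Levels of named depletion genes are CPM with TMM library sizes.

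Gene lists, 29 in all, include markers of other cell types and of RNA quality. They were tested with camera in limma at a preset correlation of 0.01, with the p-values adjusted over the lists of a comparison. The estimated correlation and fry were alternatives. A list needed 5 tested members. Named genes were fixed by rule: KIF20A, the 10 largest rises and the 10 largest falls in KIF20A_OE against EV with no overlap between libraries and at least 1 FPM in the higher group, and for each called list the 2 members with the smallest adjusted p. Parts of the rule for genes called in the depletion comparisons took none. XIST, which the rule takes among the rises, is not described, and some other genes taken by the rule are not reported here. Where 2 groups of 3 libraries are compared by exact permutation, all tests are two-sided and the smallest p possible is 0.1.

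On simulated counts with known changes, the edgeR test recovered 7.46% of 1.5-fold, 65.7% of 2-fold and 86.4% of 4-fold changes for SG1 against CTRL. For SG3 against CTRL these shares were 14.9%, 46.3% and 78.8%, for SG1 against SG3 they were 11.9%, 56.7% and 77.3%, and for the mean contrast 20.9%, 65.7% and 81.8%. The limma test recovered 1.54%, 22.4% and 90.5% for KIF20A_OE against EV. In a simulated SG1 contrast camera called a list shifted by 0.3 on the log2 scale and 0 of the other lists. Of the calls in these simulations 9.4%, 7.92%, 5.83%, 1.75% and 6.58% were false, for the comparisons in the same order. These simulations drew genes independently.

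The design, the gene lists and the rule for named genes were fixed before the data were examined, and so were the following alternatives: other size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a fit of the 6 libraries compared, a replicate block, each library left out in turn, other pseudocounts and filters, quantile and median-of-ratios scaling, moderation without trend, and an edgeR test on recovered fragments. Halved counts, limma-voom with quality weights, a filter of at least 1 CPM and per-library list scores were added after seeing the data, as were the overlap of calls between scalings and the list medians per library left out. The edgeR test on recovered fragments called 5673 genes higher and 5216 lower of 17078 tested. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.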

Results

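Libraries labelled as MDA-MB231 cells with a depletion or an overexpression of KIF20A were compared with their controls. KIF20A encodes a kinesin of the central spindle that acts in cytokinesis. The depletion dataset compared 3 CTRL libraries with 3 SG1 and 3 SG3 libraries, whose totals lay between 40.9 and 51 M (M for 1000000) counts. The overexpression dataset compared 3 EV libraries of 17 to 21 M recovered fragments with 3 libraries labelled KIF20A_OE of 16 to 22.2 M.

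KIF20A (ENSG00000112984.12) lies on the plus strand of chromosome 5, from 138178719 to 138187715 in GRCh38, and the values count the gene as a whole. Its level was 162 ± 8.75 CPM in CTRL, 121 ± 27.9 in SG1 and 75.4 ± 13.1 in SG3 (SD, n = 3 each). All CTRL libraries, at 154 to 171 CPM, lay above all SG1 libraries, at 91.5 to 147, and all SG3 libraries, at 60.8 to 86.3. The log2 fold change was -0.42 ± 0.18 (SE) for SG1 and -1.10 ± 0.18 for SG3, with edgeR quasi-likelihood adjusted p of 0.913 and 0.33 (unadjusted 0.0301 and 1.97e-05), so the reduction did not pass the threshold across all genes in either group. For SG3, DESeq2 gave an adjusted p of 0.000186, and the adjusted p over all alternatives ran from 1.85e-07, in edgeR without a low-count filter, to 1. For the mean of SG1 and SG3 the log2 fold change was -0.76 (edgeR adjusted p = 0.453), and an exact permutation of 3 against 6 libraries gave p = 0.0238. In the overexpression dataset KIF20A was 123 ± 20.9 FPM in EV and 838 ± 542 FPM in the libraries labelled KIF20A_OE (SD, n = 3 each), with single libraries at 1350, 269 and 896 FPM. The rise of 2.49 on the log2 scale passed the threshold (limma adjusted p = 0.00415), and the ratio of pooled rates was 6.36 (95% interval 6.21 to 6.53). That interval covers counting error only, not the wide spread between libraries.

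**Figure D1:**
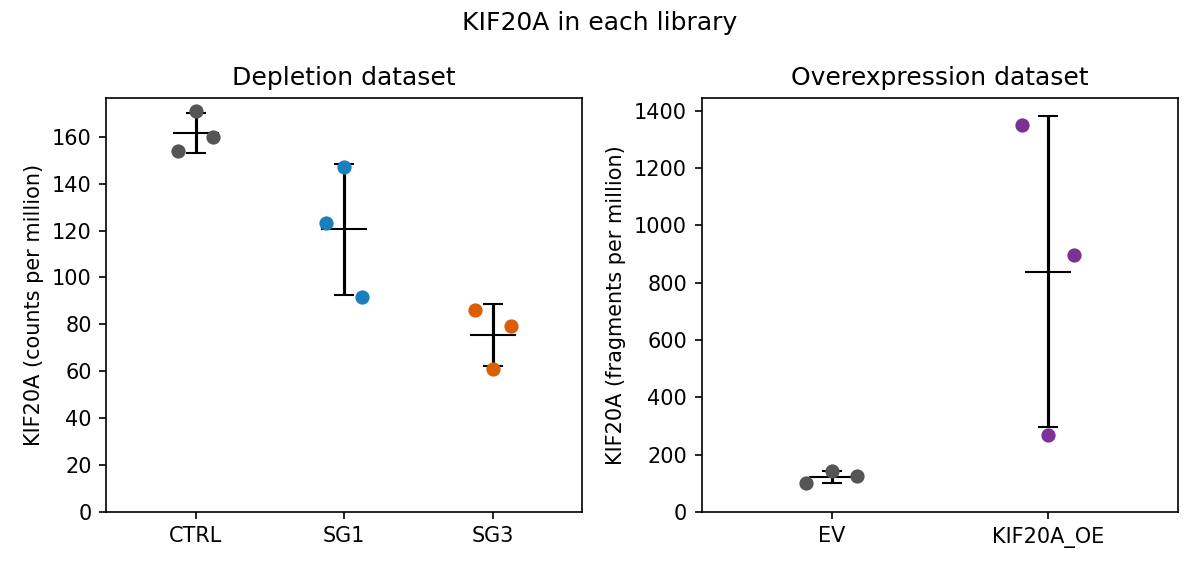
KIF20A level in each library, in CPM with TMM library sizes for the depletion dataset and in FPM for the overexpression dataset. Points are libraries and bars are group means with SD, and all SG1 and SG3 libraries (60.8 to 147 CPM) lie below the CTRL libraries (154 to 171), while the libraries labelled KIF20A_OE spread from 269 to 1350 FPM above EV at 101 to 143.

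Against CTRL, the SG1 libraries on average lay higher in mitotic genes and lower in genes of the ribosome, the respiratory chain and cholesterol synthesis, as groups and by small amounts at the preset correlation of camera. None of these calls was kept with an estimated correlation (camera adjusted p = 0.413 to 0.484). Mitosis list scores, the mean centred log2 CPM per library, were 0.229, 0.32 and -0.0176 in SG1 and -0.12, -0.0781 and 0.0824 in CTRL. They overlapped, with an exact permutation p of 0.2. Scores of the ribosomal protein, oxidative phosphorylation and cholesterol lists did not overlap, with an exact permutation p of 0.1 each, the smallest possible. Of 50 mitosis and cytokinesis genes, 44 had a positive log2 fold change (median 0.22), among them ASPM, a spindle pole protein, with 235 ± 10.2 CPM in CTRL and 329 ± 58 in SG1, and CENPF, a kinetochore protein, with 461 ± 23 and 613 ± 99.6 (SD, n = 3 each). Of 59 cytosolic ribosomal protein genes 56 were negative (median -0.19), with RPL37 at 266 ± 56.5 and 171 ± 10.5 CPM and RPLP2 at 420 ± 19.6 and 312 ± 19.2. Of 47 nuclear genes of oxidative phosphorylation 41 were negative (median -0.17), including the complex I subunits NDUFA1 at 35 ± 8.11 and 20 ± 1.93 CPM and NDUFB8 at 3.05 ± 1.11 and 1.46 ± 0.153. Of 26 cholesterol biosynthesis genes 23 were negative (median -0.23), with INSIG1, a sterol-sensing regulator, at 43.3 ± 19.9 and 26.3 ± 4.81 CPM and CYP51A1, a sterol demethylase, at 3.13 ± 1.05 and 1.6 ± 0.179. The mitochondrially encoded mRNAs, a control list for RNA quality, moved with the same group: 12 of 13 were positive (median 0.61; MT-CO2 1980 ± 757 and 3080 ± 885 CPM, MT-CYB 840 ± 472 and 1430 ± 663), and their share of counts was 1.13 to 2.84% in CTRL and 1.7 to 3.82% in SG1. Their median was 1.21 without CTRL replicate 1, 0.36 without CTRL replicate 3 and 0.29 without SG1 replicate 3. The mitosis median was 0.13 without CTRL replicate 1 or SG1 replicate 2, and the ribosomal protein and oxidative phosphorylation medians were both -0.12 without SG1 replicate 3.

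By camera, adjusted p in SG1 against CTRL was 1.35e-10 for mitosis, 2.03e-10 for ribosomal proteins, 2.55e-07 for oxidative phosphorylation, 8.98e-06 for cholesterol biosynthesis and 7.35e-07 for mitochondrially encoded mRNAs. With an estimated correlation these lists had camera adjusted p of 0.459, 0.484, 0.459, 0.413 and 0.475, so none kept its call. Smaller calls were higher kinesins (median 0.16; KIF20B 180 ± 36.1 and 248 ± 23 CPM, CENPE 152 ± 25 and 207 ± 38.6), homologous recombination genes (0.13; ATR 53.1 ± 6.59 and 69.4 ± 1.68, BRCA2 35.4 ± 4.34 and 47.3 ± 7.13) and hypoxia and glycolysis genes (0.12; ANGPTL4 1.2 ± 0.195 and 4.74 ± 3.18, PDK3 25.6 ± 1.37 and 37.1 ± 5.01). Their camera adjusted p was 0.00194, 0.00231 and 0.0353, and with an estimated correlation adjusted p = 0.44, 0.714 and 0.714. Lower calls were DNA replication (median -0.06; UNG 117 ± 9.2 and 85.8 ± 2.76 CPM, MCM5 132 ± 9.35 and 104 ± 5.05), unfolded protein and integrated stress response (-0.13; SDF2L1 21.1 ± 3.95 and 15.6 ± 2.08, SLC3A2 296 ± 21.2 and 235 ± 31.6) and fatty acid synthesis (-0.06; SCD 191 ± 71.8 and 86.6 ± 39.8, FADS2 108 ± 13.5 and 81.4 ± 13.8). Their camera adjusted p was 0.036, 0.00194 and 0.036, and with an estimated correlation adjusted p = 0.754, 0.459 and 0.465. Control lists of fibroblast markers (median -0.47; C1S 2.43 ± 0.794 and 1.16 ± 0.226 CPM, PDGFRB 14.6 ± 2.51 and 10.2 ± 0.984) and luminal markers (-0.27; KRT8 742 ± 69.3 and 594 ± 113, and in the other direction SPDEF 0.55 ± 0.214 and 1.38 ± 0.858) were also called lower, with camera adjusted p of 0.00526 and 0.0127, and adjusted p = 0.44 and 0.475 with an estimated correlation. With a library left out, camera calls ended for DNA replication (CTRL replicate 3, SG1 replicates 1 and 3, adjusted p up to 0.891), homologous recombination (CTRL replicate 2, 0.313), the stress response (CTRL replicate 3, SG1 replicate 2, up to 0.342) and hypoxia (CTRL replicates 1 and 3, SG1 replicates 1 and 2, up to 0.857). Over all libraries left out, their medians ran from -0.13 to 0.02, 0.04 to 0.22, -0.24 to -0.05 and 0.004 to 0.27 in turn. The kinesin median was 0.09 without CTRL replicate 1 and the fibroblast median -0.23 without SG1 replicate 3, where both calls held (camera adjusted p = 0.00973 and 0.0456). Calls also ended for fatty acids (CTRL replicates 1 and 3, SG1 replicates 1 and 3, SG3 replicate 1, up to 0.263, and in the fit of only the 6 libraries compared) and luminal markers (CTRL replicate 2, SG1 replicate 3, up to 0.131). The medians of these 2 lists ran from -0.12 to -0.02 and from -0.40 to -0.16 with a library left out. The other lists had camera adjusted p of 0.123 to 0.764. Among them, the median, the mean and the test differed in sign for the matrix, NF-kB, actin and endothelial lists.

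Single genes of SG1 did not pass: edgeR called 0 of 16786 genes, with 770 at an unadjusted p under 0.05 where chance gives 839. DESeq2 called 3 genes, all higher, namely ROBO1, PDK4 and ANGPTL4, and limma-voom called 0, or 13 higher and 30 lower with quality weights. Without a low-count filter edgeR called 26 higher and 65 lower. Adjusted over the list alone, MMP1 and ANGPTL4 rose in the matrix and hypoxia lists, and SCD, PMEPA1 and CD14 fell in the fatty acid, TGF-beta and leukocyte lists, and 0 members of the other lists did either. These names and the DESeq2 calls were taken after their values were seen. The unadjusted count was 330 without CTRL replicate 2, 2021 without CTRL replicate 3 and 1529 without SG3 replicate 1, and without SG1 replicate 2 edgeR called 1 gene, ABCG1, lower.

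In SG3, genes of the stress response, the ribosome and cholesterol synthesis were lower than in CTRL as groups, and here mitotic genes lay slightly lower, at the preset correlation of camera. None of these calls was kept with an estimated correlation (camera adjusted p = 0.109 to 0.835). By exact permutation of the list scores per library, p was 0.1 for the stress response and cholesterol, and 0.4 for ribosomal proteins and mitosis. Of 36 unfolded protein and integrated stress response genes 34 were negative (median -0.29), among them XBP1, a transcription factor of the unfolded protein response, with 118 ± 20.1 CPM in CTRL and 90.6 ± 1.45 in SG3, and CEBPG, with 53.6 ± 8.14 and 41.1 ± 1.51 (SD, n = 3 each). Of 59 ribosomal protein genes 58 were negative (median -0.16; RPS29 97.8 ± 20.9 and 70 ± 7.88 CPM, RPL38 108 ± 6.47 and 89.5 ± 16.2). Of 26 cholesterol genes 25 were negative (median -0.17), with INSIG1 at 43.3 ± 19.9 and 24.7 ± 5.74 CPM and SREBF2, the activator of the pathway, at 106 ± 4.3 and 86.7 ± 4.55. Of 23 fatty acid synthesis genes 16 were negative (median -0.08), with the desaturase gene SCD at 191 ± 71.8 and 70.7 ± 15.8 CPM and the activator gene SREBF1 at 172 ± 25.8 and 107 ± 18.1.

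Mitosis genes were negative in 45 of 50 cases in SG3 (median -0.09; KIF23 211 ± 37.4 and 177 ± 9.86 CPM, NDC80 97.8 ± 19.4 and 82.2 ± 4.07). Oxidative phosphorylation (median -0.11; UQCRQ 55.4 ± 6.54 and 46.7 ± 3.07 CPM, COX7C 111 ± 11.4 and 98.5 ± 4.29), MYC targets (-0.09; HSPE1 28.6 ± 5.17 and 23.2 ± 3.41, NPM1 1260 ± 338 and 1040 ± 71.4), antigen presentation (-0.11; HLA-F 6.23 ± 2.89 and 4.41 ± 1.19, HLA-DRA 65.3 ± 1.49 and 56.1 ± 6.78) and luminal control markers (-0.20; GATA3 30.1 ± 1.46 and 24.1 ± 3.62, and XBP1 again) were called lower too. Camera adjusted p was 5.63e-14 for the stress response, 2.03e-14 for ribosomal proteins, 2.98e-07 for cholesterol, 0.00205 for fatty acids, 7.45e-05 for mitosis, 3.89e-05 for oxidative phosphorylation, 0.00253 for MYC targets, 0.0477 for antigen presentation and 0.000443 for luminal markers. With an estimated correlation the same lists, in that order, had adjusted p = 0.109, 0.713, 0.109, 0.417, 0.835, 0.747, 0.984, 0.984 and 0.535, so none kept its call. The other lists had camera adjusted p of 0.0547 to 0.977, and among them the mitochondrially encoded mRNAs had a median of -0.16 (adjusted p = 0.409), which was 0.43 without CTRL replicate 1 and 0.03 without SG3 replicate 3. It was called lower without SG3 replicate 1 (-0.52), CTRL replicate 3 (-0.42) or CTRL replicate 2 (-0.29), with camera adjusted p of 0.00196, 0.000766 and 0.00769, and higher without CTRL replicate 1 (0.000669). Median, mean and test differed in sign for the kinesin, p53, YAP, matrix, immediate early, NRF2, TGF-beta, leukocyte and endothelial lists. Without SG3 replicate 1, camera calls ended for mitosis (adjusted p = 0.313), oxidative phosphorylation (0.825), MYC targets (0.703), ribosomal proteins (0.211) and luminal markers (0.677, and also with no low-count filter). Without CTRL replicate 3 they ended for mitosis (camera adjusted p = 0.339), MYC targets (0.336) and fatty acids (0.0569, and 0.0811 without CTRL replicate 1). With a library left out, medians ran from -0.16 to -0.05 for mitosis, -0.16 to -0.003 for oxidative phosphorylation and -0.18 to 0.01 for MYC targets. They were -0.24 to -0.07 for ribosomal proteins, -0.38 to -0.03 for luminal markers and -0.08 to -0.04 for fatty acids. The antigen presentation call held in 9 of 16 alternatives, not without CTRL replicate 1 or 2, SG1 replicate 2 or SG3 replicate 1, and its median was positive in 2 of them.

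For single genes of SG3, edgeR called 0 of 16786, with 200 at an unadjusted p under 0.05 where chance gives 839. Libraries of a group lay apart on the first principal component, with SG3 replicate 1 at 32.1 against -33.36 and -29.99. CTRL replicate 3 was at 24.71 against -27.42 and -21.3, while SG1 lay at 16.61 to 22.02. Correlations were 0.979 to 0.989 within groups and 0.98 to 0.99 between them. With this spread inside groups, 0 calls do not show that no gene changed. DESeq2 called PDK4, CPT1A and ANGPTL4 higher and KIF20A lower, and limma-voom called 0, or KIF20A alone with quality weights. Without a low-count filter edgeR called 5 higher and 3 lower. Adjusted over the list alone, ANGPTL4 rose and SCD fell, and 0 other list members did either. These names were taken after their values were seen, except KIF20A. Without SG3 replicate 1 camera called 5 lists instead of 9, and the unadjusted count was 460. It was 440 without CTRL replicate 1.

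Set against each other, SG1 and SG3 differed most in mitotic genes and in the control lists for RNA quality, at the preset correlation of camera. With an estimated correlation no list was called (camera adjusted p = 0.658 or more). Of the 50 mitosis genes 47 were higher in SG1 than in SG3 (median log2 difference 0.34), and all 13 mitochondrially encoded mRNAs were higher (median 0.79). Homologous recombination genes (median 0.16, 25 of 30 positive) and kinesins (median 0.06, 19 of 31 positive) were higher as well, and 6 transcripts lacking a poly(A) tail were all lower (median -0.45). The camera adjusted p was 1.02e-20, 1.46e-08, 0.00101, 0.0116 and 0.0318 for these lists in turn, and adjusted p = 0.658, 0.658, 0.909, 0.658 and 0.658 with an estimated correlation, so none kept its call. Camera adjusted p for the other lists was 0.0558 to 0.926, and median, mean and test differed in sign for the matrix, NF-kB, immediate early, fatty acid, ribosomal protein, actin and endothelial lists. Without SG1 replicate 2 the mitosis median was 0.22, without SG1 replicate 3 the mitochondrial median was 0.44, and without SG3 replicate 2 the recombination median was 0.09. The kinesin call ended without SG1 replicate 1 or SG3 replicate 1 (camera adjusted p = 0.0731 and 0.145), and that of the transcripts lacking a poly(A) tail held in 7 of 16 alternatives (up to 0.433). The median of the latter was -0.80 to -0.32 with a library left out. The KIF20A difference was 0.68 on the log2 scale (edgeR adjusted p = 0.861).

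Between SG1 and SG3 edgeR called 0 of 16786 genes, with 795 at an unadjusted p under 0.05 where chance gives 839. DESeq2 called 2 higher and 3 lower (ODAPH, MANCR, KRT81, HCN4 and FAM133A, chosen after their values were seen), and limma-voom called 0. With quality weights limma-voom called 857 higher and 926 lower, and without a low-count filter edgeR called 23 and 54. Adjusted over the list alone, KIF23, ASPM and NUF2 of the mitosis list, KIF23 of the kinesin list and HLA-DRA of the antigen presentation list were higher in SG1, and JUNB, PDGFRB and C1S of the immediate early and fibroblast lists were lower. Without SG3 replicate 1 the unadjusted count was 3080 and edgeR called 5 genes lower in SG1 (GPX1, POLR2L, SAA1, KRT81 and BEX3). It was 372 without SG3 replicate 2 and 422 without SG3 replicate 3.

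For the mean of SG1 and SG3, the genes with the lowest unadjusted p of that contrast were PDK4, CPT1A, ANGPTL4 and SCD (3.89e-05 to 0.000111), ahead of KIF20A (0.000135). PDK4, CPT1A, ANGPTL4 and SCD act in fatty acid use, and they were grouped, with PLIN2 and TGFA, after the values were seen and without an enrichment test. PDK4, a kinase that restrains glucose oxidation, had 2.26 ± 1.04 CPM in CTRL (SD, n = 3) and 7.13 ± 1.15 in the depleted libraries (SD, n = 6). CPT1A, the carnitine transferase that admits fatty acids to mitochondria, had 54.3 ± 13.9 and 99.8 ± 9.98 CPM, and ANGPTL4, a secreted lipase inhibitor, 1.2 ± 0.195 and 5.2 ± 2.62. PLIN2, a lipid droplet protein, had 53.7 ± 8.66 and 79.2 ± 13.1 CPM, and TGFA, an epidermal growth factor receptor ligand, 101 ± 3.64 and 141 ± 8.33. SCD had 191 ± 71.8 and 78.6 ± 28.4 CPM. For these genes the log2 fold changes were 1.65, 0.88, 2.10, 0.56, 0.49 and -1.29, and the edgeR adjusted p was 0.453 for PDK4, CPT1A, ANGPTL4 and SCD and 1 for PLIN2 and TGFA.

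**Figure D2:**
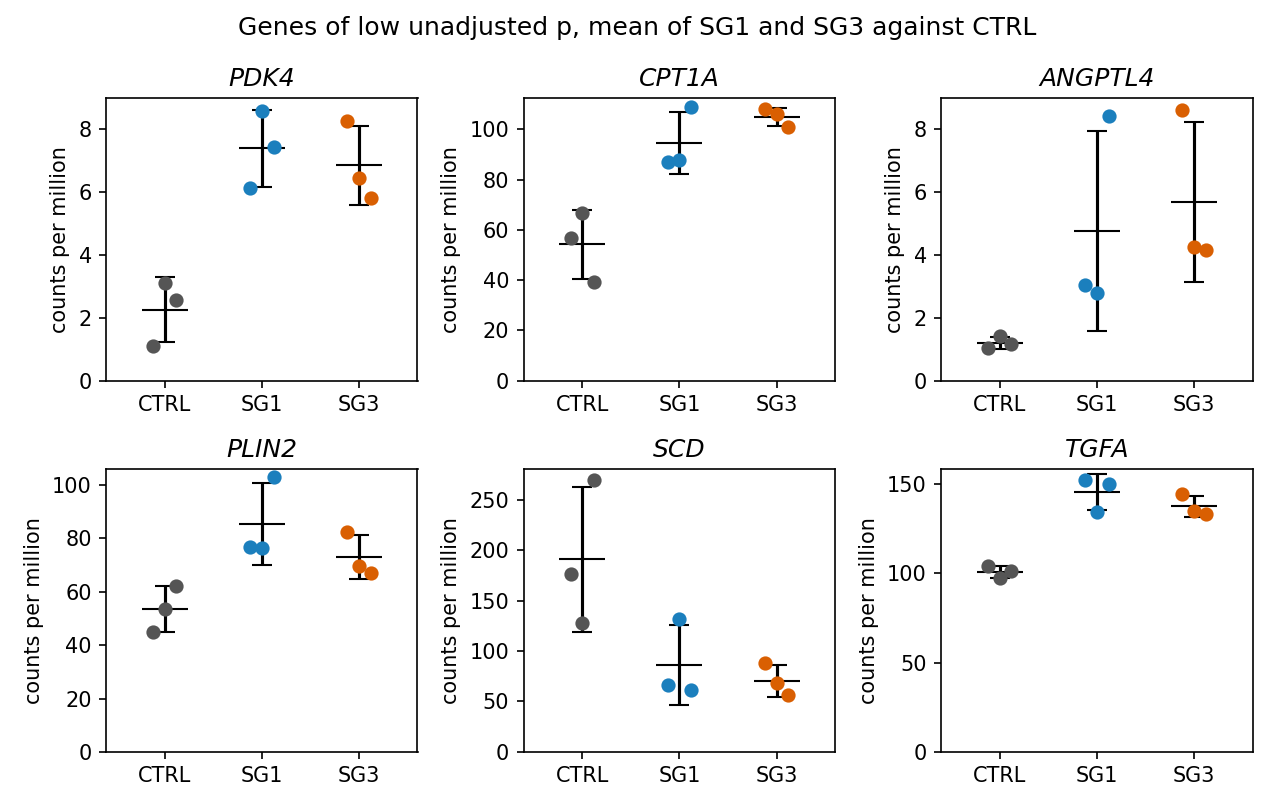
Levels in CPM of PDK4, CPT1A, ANGPTL4, PLIN2, SCD and TGFA in each of the 9 depletion libraries, with points for libraries and bars for group means with SD. The depleted libraries reach 5.83 to 8.6 CPM of PDK4 against 1.1 to 3.12 in CTRL, and SCD in SG1 replicate 2, at 132 CPM, overlaps the CTRL range of 128 to 269.

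For the mean of SG1 and SG3, edgeR called 0 of 16786 genes, with 295 at an unadjusted p under 0.05 where chance gives 839. DESeq2 called TGFA, PDK4, CPT1A and ANGPTL4 higher and KIF20A lower, and limma-voom called 0, or 4 higher and 2 lower with quality weights. Without a low-count filter edgeR called 11 higher and 9 lower. Over the list alone MMP1 and ANGPTL4 rose, and SCD, SREBF1 and CD14 fell. All 59 ribosomal protein genes were negative (median -0.17), as were 44 of 47 oxidative phosphorylation, 24 of 26 cholesterol (median -0.20) and 32 of 36 stress response genes (median -0.24). Their camera adjusted p was 1.17e-16, 6.94e-09, 8e-09 and 1.55e-09, and with an estimated correlation adjusted p = 0.369, 0.36, 0.142 and 0.157. Control lists of other cell types were lower too, with medians of -0.39 for fibroblast and -0.24 for luminal markers (camera adjusted p = 0.0186 and 0.000359, and 0.36 for both with an estimated correlation). The fibroblast call ended without CTRL replicate 1 or 2, SG1 replicate 3 or SG3 replicate 3 (camera adjusted p = 0.0697 to 0.265), and the luminal median was -0.11 without CTRL replicate 2, where the fibroblast median was -0.22. In all, camera called 13 of 29 lists at the preset correlation and 0 with the estimated one, and 6 without CTRL replicate 1. The other lists had camera adjusted p of 0.0719 to 0.937, and median, mean and test differed in sign for the matrix, interferon, NF-kB, NRF2, leukocyte and endothelial lists. The mitochondrially encoded mRNAs (median 0.25) and the mitosis list (0.05) were among the lists called higher. Their medians changed sign without CTRL replicate 3 (-0.03) and without CTRL replicate 1 (-0.02), in that order. With another library left out, the medians of these 2 lists reached as much as 0.84 and 0.13. Their camera calls ended without CTRL replicate 2 or 3, SG1 replicate 3 or SG3 replicate 1 (adjusted p up to 0.967), and without CTRL replicate 1 or 2, SG1 replicate 1 or 2 or SG3 replicate 3 (up to 0.779). Without SG1 replicate 2 edgeR called SCD and ABCG1 lower, and the unadjusted count was 501 without CTRL replicate 1, 183 without CTRL replicate 2 and 836 without CTRL replicate 3.

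No gene was called in both SG1 and SG3 by edgeR, and DESeq2 called 2 higher in both, PDK4 and ANGPTL4. Fold changes of SG1 and SG3 over the same controls correlated across the 16786 genes, which are not independent replicates, with r = 0.417. In 20 simulations of unchanged groups against those controls r was 0.502 (0.479 to 0.525). The covariance was 0.0537 against a simulated 0.0711, a difference of -0.0174, and 59.4% of genes had the same sign against 66.8%. All observed values lay below the simulated ones. Shared controls can thus give a similarity at least this large. The simulations drew genes independently and overshot the observed values, so they did not match these libraries. They cannot show whether a small set of genes moved in both groups. With 3 control libraries no split of the controls was made.

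Libraries labelled KIF20A_OE and EV differed in most genes tested. Of 15265 genes, limma called 7048 higher and 3573 lower in KIF20A_OE, 1416 of them by more than 8-fold, and 4644 did not pass. IRS4, an insulin receptor substrate, gave no fragment in EV and 1570 ± 305 FPM in KIF20A_OE (SD, n = 3), at least 10200-fold higher. CDKN2A, which encodes cell cycle inhibitors, the homeobox gene HOXD13, the ubiquitin hydrolase gene UCHL1 and the zinc finger gene ZNF711 also had no fragment in EV and were at least 2080-fold, 999-fold, 946-fold and 925-fold higher. AMOT, an angiomotin, had a ratio of 6780 (95% interval 2910 to 20900), NID1, a basement membrane protein, 6370 (1760 to 52600), the lactate transporter gene SLC16A1 1700 (922 to 3540) and PTGFRN 1160 (591 to 2700). In the other direction, APCDD1L had 351 ± 57.5 FPM in EV and no fragment in KIF20A_OE, at least 2180-fold lower. Ratios of EV to KIF20A_OE were 71500 for the cystatin gene CST1 (12800 to 2820000), 23400 for keratin gene KRT19 (6490 to 193000) and 4400 for the surface nucleotidase gene NT5E (2710 to 7690). They were 1470 for the urokinase gene PLAU (1010 to 2220), 1250 for the receptor kinase gene AXL (934 to 1730), 1150 for CD44 (818 to 1690), 795 for S100A6 (613 to 1050) and 484 for MYOF (396 to 598). All of these genes passed with limma adjusted p from 4.91e-09 to 7.21e-08. Their intervals cover counting error only, not the spread between libraries.

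These libraries also stood apart as wholes. Across genes, which are not independent replicates, log values correlated with r = 0.698 to 0.724 between EV and KIF20A_OE and 0.975 to 0.989 within each group, and the first principal component held 91.6% of the variance. Correlations with the depletion libraries were 0.906 to 0.92 for EV and 0.795 to 0.81 for KIF20A_OE, across tables scaled separately. In 74.1% of genes the EV and KIF20A_OE libraries did not overlap, where chance gives 10%. The share of higher calls was 66.4%, but 54.3% with quantile normalization (5547 higher, 4666 lower), 52% with median-of-ratios scaling (5296 and 4894) and 52.1% with edgeR on recovered fragments (5673 and 5216). The median log2 fold change of all genes was 0.37, and those settings shifted it by -0.28, -0.32 and -0.30. Of the 10621 calls, 84.9%, 83.5% and 80.7% were kept by gene and direction in these settings and 0 were reversed. Of the higher calls 77.7%, 75.1% and 71% were kept. No list called below was called in the other direction under these scalings.

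Genes of adhesion, matrix and inflammation fell in the libraries labelled KIF20A_OE, which stand apart from EV as above. With an estimated correlation these list calls were lost (camera adjusted p = 0.162 to 0.47). Among extracellular matrix genes 26 of 37 fell and 7 rose (median -3.15), with PLAU from 704 ± 99.7 to 0.457 ± 0.181 FPM (SD, n = 3 each). Among actin and focal adhesion genes 30 of 41 fell and 5 rose (median -1.47), with the integrin genes ITGA3 from 1960 ± 214 to 16.7 ± 0.815 FPM and ITGA2 from 673 ± 89.6 to 14.4 ± 1.85. Of 24 YAP and TEAD targets 20 fell and 2 rose (median -2.27), with NT5E from 1240 ± 42.7 to 0.275 ± 0.152 FPM and AXL from 962 ± 148 to 0.771 ± 0.0352. Mesenchymal genes (16 of 28 fell, 7 rose, median -2.45; AXL), epithelial genes (15 of 23 fell, 6 rose, median -1.06; KRT19 and KRT7, the latter from 287 ± 45 to 0.0958 ± 0.0907 FPM) and TGF-beta targets (15 of 26 fell, 5 rose, median -0.88; TGFBI from 212 ± 20.7 to 0.286 ± 0.206) moved the same way. Camera adjusted p was 4.98e-09, 3.02e-09, 3.02e-09, 0.000118, 0.000367 and 0.000367 in that order, and with an estimated correlation adjusted p = 0.24, 0.162, 0.162, 0.438, 0.447 and 0.47. The counts and medians are those of the authors' scaling. Over all alternatives the medians, in the same order, were -3.55 to -2.99, -1.84 to -1.37, -2.67 to -2.04, -2.83 to -2.19, -1.95 to -0.62 and -1.25 to -0.60.

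Interferon stimulated genes fell in 33 of 38 cases and rose in 2 (median -1.87), with PARP14 from 56.9 ± 4.41 FPM to no fragment and the antiviral gene IFIT3 from 70 ± 5.99 to 2.91 ± 0.247. This call and those of the next lists were lost with an estimated correlation (camera adjusted p = 0.24 to 0.639). NF-kB targets fell in 21 of 26 cases and rose in 1 (median -1.71, or -1.89 with genes lacking fragments set to their bound), with BIRC3 from 50.5 ± 12.8 to 0.539 ± 0.345 FPM and TNFAIP2 from 115 ± 28.6 to 3.56 ± 1.15. Antigen presentation genes (15 of 25 fell, 4 rose, median -0.86, or -1.68 to -0.81 over all alternatives) included the proteasome subunit gene PSMB8, from 43.6 ± 5.25 to 0.0566 ± 0.0538 FPM, and CD274, from 27.3 ± 3.92 to 0.94 ± 0.437. Hypoxia and glycolysis genes (26 of 38 fell, 4 rose, median -0.94) included the lactate exporter gene SLC16A3, from 619 ± 67.8 to 3.88 ± 0.122 FPM, and ANGPTL4, from 148 ± 93 to 0.672 ± 0.45. Immediate early genes (14 of 29 fell, 9 rose, median -0.36; DUSP6 419 ± 68.8 to 0.798 ± 0.263 FPM, FOSL1 324 ± 70.4 to 1.67 ± 0.419) and cholesterol genes (10 of 26 fell, 4 rose, median -0.18) were also called lower. Camera adjusted p was 1.3e-10, 4.84e-09, 0.000142, 1.82e-06, 0.0208 and 0.0193 in that order, and with an estimated correlation adjusted p = 0.24, 0.24, 0.438, 0.47, 0.639 and 0.639. Quantile normalization ended the calls of the immediate early and cholesterol lists, and median-of-ratios scaling, the edgeR test, EV replicate 1 left out or KIF20A_OE replicate 2 left out ended the former. Over all alternatives the medians were -2.60 to -1.71 for interferon, -2.96 to -1.23 for NF-kB, -1.40 to -0.79 for hypoxia, -0.71 to -0.26 for immediate early and -0.59 to -0.07 for cholesterol genes. Luminal control markers (6 of 14 fell, 3 rose, median -1.09; MLPH 153 ± 34.5 to 0.0301 ± 0.0521 FPM) and endothelial control markers (6 of 8 fell, 1 rose, median -2.40; ESAM 210 ± 39.2 to 1.66 ± 0.289, TIE1 70.5 ± 9.16 to 0.0301 ± 0.0521) moved with these groups, with camera adjusted p of 0.0103 and 0.00178, and adjusted p = 0.47 and 0.438 with an estimated correlation. Over all alternatives their medians were -1.92 to -0.80 and -6.13 to -1.19.

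Genes of DNA replication, repair, respiration and ribosome production rose in the same libraries, which differ from EV along the component that holds 91.6% of the variance. These list calls were not kept with an estimated correlation (camera adjusted p = 0.47 to 0.658). Of 51 DNA replication genes 42 rose and 0 fell (median 1.19), with the polymerase subunit gene POLA2 from 3.58 ± 0.212 to 23.9 ± 2.12 FPM and the kinase gene CDC7 from 33.6 ± 7.3 to 161 ± 8.48 (SD, n = 3 each). Of 30 recombination and repair genes 23 rose and 1 fell (median 1.01), with the nuclease gene EXO1 from 28.4 ± 9.33 to 199 ± 18.1 FPM and POLQ from 11.9 ± 4.53 to 64 ± 4.7. Targets of p53 rose in 21 of 32 cases and fell in 3 (median 1.11), with CYFIP2 from 2.13 ± 1.57 to 168 ± 46.2 FPM and EDA2R from 0.157 ± 0.272 to 23.1 ± 3.34. Oxidative phosphorylation genes (38 of 46 rose, 0 fell, median 0.68) included NDUFB9, from 30.6 ± 3.88 to 127 ± 11 FPM, and NDUFB10, from 68.6 ± 3.64 to 243 ± 32.7. MYC targets (30 of 39 rose, 0 fell, median 0.93) included POLR1B, from 38.2 ± 2.35 to 109 ± 6.82 FPM, and the chaperonin gene HSPD1, from 336 ± 60.9 to 1110 ± 127. Ribosomal protein genes (45 of 59 rose, 0 fell, median 0.57) included RPS2, from 876 ± 147 to 3200 ± 376 FPM, and RPS15, from 357 ± 39.5 to 850 ± 64.1. Camera adjusted p was 0.000204, 0.00787, 0.0167, 0.00118, 0.00177 and 0.00269 in that order, and with an estimated correlation adjusted p = 0.639, 0.658, 0.639, 0.47, 0.639 and 0.658. Median-of-ratios scaling and the edgeR test ended the calls of the ribosomal protein and luminal lists. Over all alternatives the lowest medians were 0.81, 0.70, 0.77, 0.32, 0.56 and 0.20 in the same order, while with a library left out those of oxidative phosphorylation and ribosomal proteins stayed at 0.64 and 0.50 or above.

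Mitosis genes, of the process in which KIF20A acts, were not called as a list in KIF20A_OE: 25 of 49 rose and 5 fell (median 0.53, or 0.15 to 0.72 over all alternatives, camera adjusted p = 0.42). The other kinesins (14 of 35 rose, 7 fell), the stress response (18 of 36 rose, 7 fell), fatty acid synthesis (8 of 23 rose, 11 fell) and NRF2 targets (7 of 28 rose, 11 fell) were not called either, with camera adjusted p of 0.824, 0.496, 0.0542 and 0.0725. Control lists of leukocyte markers (3 of 7 rose, 1 fell), fibroblast markers (5 of 8 rose, 3 fell) and transcripts lacking a poly(A) tail (1 of 5 rose, 2 fell) had camera adjusted p of 0.858, 0.824 and 0.422, and the median of the fibroblast list (1.12) was opposite in sign to its test. Adjusted over the list alone the counts of all 28 lists stayed within 2 genes of those over all genes.

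A block of neighbouring genes in 9p21 gave no fragment in EV and no count in the depletion libraries, and was expressed in the libraries labelled KIF20A_OE. It runs from MTAP, which starts at 21802543 on chromosome 9 of GRCh38, over CDKN2A, CDKN2B and DMRTA1 to ELAVL2, which ends at 23826337. EV held 58.7 M fragments and the depletion libraries 423 M counts. In KIF20A_OE, MTAP, a methionine salvage enzyme, was at 23.3 ± 1.13 FPM, CDKN2A at 322 ± 40.9, CDKN2B at 13.6 ± 1.35, DMRTA1 at 4.21 ± 1.52 and ELAVL2 at 15.7 ± 0.864 (SD, n = 3). KLHL9, on the side towards the telomere, had 0 counts in the depletion libraries, 15 fragments in EV and 149 ± 7.26 FPM in KIF20A_OE. The flanking FOCAD and MLLT3 were expressed in both groups, at 4.74 ± 0.866 and 86 ± 9.2 FPM and at 28.6 ± 2.18 and 64.8 ± 7.84. This block was chosen after its values were seen.

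**Figure D3:**
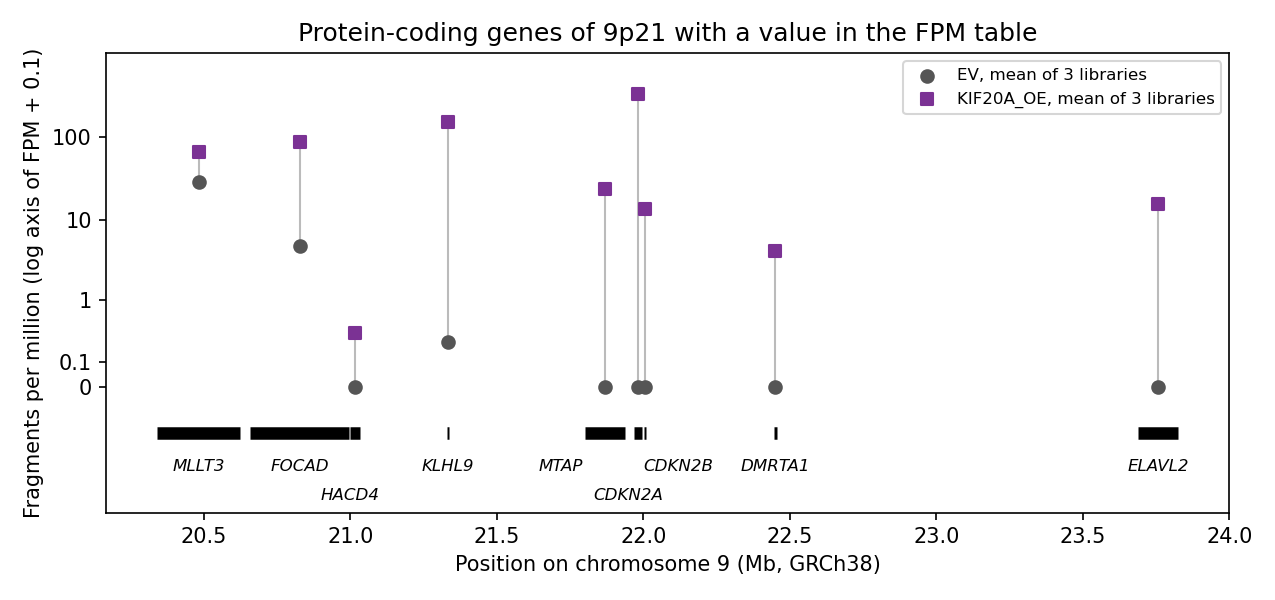
Mean FPM of the EV and KIF20A_OE libraries on a log axis of FPM + 0.1, placed at the midpoints of the protein-coding genes of 9p21 that have a value, against position on chromosome 9 (GRCh38), with gene extents as bars. MTAP, CDKN2A, CDKN2B, DMRTA1 and ELAVL2 are at 0 in EV and at 4.21 to 322 FPM in KIF20A_OE.

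KIF20A_OE against EV and the depletion comparisons were searched for genes that moved in opposite directions. Limma called 69.6% of genes in KIF20A_OE, and these libraries correlated with the depletion libraries at r = 0.795 to 0.81 against 0.906 to 0.92 for EV, so an opposite fold change need not come from KIF20A. Over 13676 genes tested in both datasets, 0 were called in KIF20A_OE and, with the other sign, in both SG1 and SG3 by limma and edgeR, and 0 with the same sign. With DESeq2 for the depletion comparisons the opposite count was 2. Across genes, fold changes of KIF20A_OE correlated with those of SG1 at r = -0.0871, of SG3 at r = -0.00127 and of their mean at r = -0.0594. Of 158 genes called in KIF20A_OE and at an unadjusted p under 0.05 in the mean contrast, 86 moved in opposite directions and 72 in the same direction (Fisher's exact p = 0.338). PDK4, ANGPTL4 and TGFA fell in KIF20A_OE, with log2 fold changes of -1.21, -6.34 and -5.10, while SCD rose by 0.61, with limma adjusted p of 0.00489, 3.06e-06, 7.2e-07 and 0.0204. CPT1A (0.05, limma adjusted p = 0.845) and PLIN2 (-0.60, adjusted p = 0.097) did not pass.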

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

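The explanations of the division of SG1 from SG3 were chosen after the result was seen, while the contrast itself, the estimated correlation, the libraries left out in turn and the splits were planned. SG1 stood above SG3 in mitosis genes (median log2 difference 0.341), kinesins (0.0598), homologous recombination genes (0.162) and mitochondrially encoded mRNAs (0.793), and below it in transcripts lacking a poly(A) tail (-0.448), although both groups carry the same label of KIF20A depletion. Members of the mitosis list had an estimated correlation of 0.353 in the contrasts with CTRL. With estimated correlations camera gave this list, kinesins, mitochondrially encoded mRNAs and transcripts lacking a poly(A) tail an adjusted p of 0.658. The recombination genes had 0.909, so these calls may rest on genes that move together within groups. The DNA replication list, which also follows cycling, was not called (median -0.011, camera adjusted p = 0.551). A single library is less likely as the source of the mitosis difference, because its median stayed at 0.218 or above with any library left out. The kinesin call ended without SG1 replicate 1 (median 0.0692) or SG3 replicate 1 (0.141), where the median was not smaller than 0.0598. The poly(A) call held in only 7 of 16 alternatives. Its median stayed at -0.803 to -0.316 with any library left out, so its lost calls do not point to a single library. Between the groups the mitochondrially encoded mRNAs moved with the mitosis list. Within each group the library with the highest mitochondrial score had the lowest mitosis score, as SG1 replicate 3 (1 and -0.0176) and SG3 replicate 1 (0.279 and -0.231). Both control lists for RNA quality differed between SG1 and SG3. With 3 libraries per group and no test, these scores cannot decide whether RNA quality is a source. KIF20A, at 121 CPM in SG1 and 75.4 CPM in SG3, was not shown to be the cause.

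Other splits of the same libraries into equal groups show how many genes and lists arise without the labels, and with 10 splits each they are too few for a share under 0.05. For SG1 against CTRL the real split gave 770 genes at an unadjusted p under 0.05 and the highest other split 1872, with 5 of 10 splits as large. For its lists the values were 13 and 14, with 3 of 10 as large. For SG3 against CTRL they were 200 and 2924 genes, with 9 of 10 as large, and 9 and 13 lists, with 6 of 10. For SG1 against SG3 they were 795 and 2224 genes, with 4 of 10, and 5 and 12 lists, with 10 of 10 as large.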

How the results depend on the processing

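For SG1 against CTRL, DESeq2 called 3 genes higher and 0 lower, no filter on low counts gave 26 and 65, and limma-voom with quality weights gave 13 and 30. For SG3 against CTRL these were 3 and 1, 5 and 3, and 0 and 1. For SG1 against SG3 they were 2 and 3, 23 and 54, and 857 and 926, and for the mean of SG1 and SG3 they were 4 and 1, 11 and 9, and 4 and 2. Genes higher in both groups numbered 2 with DESeq2 and 4 without a filter, where 1 was lower in both. DESeq2 gave 2 genes opposite to overexpression. Without a filter 31103 genes were tested, and the smallest edgeR adjusted p was 1.67e-50 in SG1 and 3.03e-27 in SG3. With the filter it was 0.913 and 0.33, so the calls without a filter are uncertain. The cause of these differences was not tested.

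KIF20A passed the threshold in SG3 with DESeq2 (-1.09), without a filter (-1.07) and with quality weights (-1.23), where edgeR gave -1.10 and did not pass. Between SG1 and SG3 it passed without a filter (0.643) and with quality weights (0.753), and in the mean contrast with DESeq2 (-0.759), without a filter (-0.75) and with quality weights (-0.856). In SG1 it passed in 0 of 19 alternatives, at -0.588 to -0.257. In KIF20A_OE it passed in 14 of 14, at 2.01 to 3.17.

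With each library left out in turn, edgeR called 0 to 1 genes lower in SG1, the 1 without SG1 replicate 2. It called 0 to 5 lower in SG1 against SG3, the 5 without SG3 replicate 1, and 0 to 2 lower in the mean contrast, the 2 without SG1 replicate 2. Calls in KIF20A_OE ran from 6314 to 7056 higher and from 3269 to 3422 lower. Lists called numbered 11 to 15 in SG1, 5 to 13 in SG3, 4 to 10 in SG1 against SG3, 6 to 15 in the mean contrast and 19 to 21 in KIF20A_OE. The lowest of SG3 was 5 without SG3 replicate 1, and that of the mean contrast 6 without CTRL replicate 1. SG1 against SG3 gave 8 without SG1 replicate 2, 8 without SG3 replicate 2 and 10 without SG3 replicate 3.

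With an estimated correlation camera called 0 lists in SG1, 0 in SG3, 0 in SG1 against SG3, 0 in the mean contrast and 0 in KIF20A_OE, and fry called 0, 0, 0, 0 and 25. With looser filters the median log2 fold change in KIF20A_OE shifted by -0.163 (no filter) and -0.106 (mean of at least 0.1 FPM). Of 1009 values of named genes in the depletion contrasts 983 stayed short of the threshold, 26 passed it and 0 reversed, and in KIF20A_OE 728 of 728 kept theirs. Replicate numbers did not pair in the depletion dataset, with correlations of deviations at -0.123 to 0.182 for same numbers and -0.159 to 0.182 for different numbers. In the overexpression dataset they were 0.0142 to 0.0577 and -0.0497 to 0.0093. Same numbers were thus higher there, by small amounts, and a weak pairing stays open. A replicate block gave 0 genes in each depletion contrast and 6984 higher and 3546 lower in KIF20A_OE.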

Other observations

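The neighbouring silent genes, the marker genes, the component as a covariate and the overlap of calls were chosen after the result was seen, while the other scalings and the splits were planned and the test of PPAR targets was written before its values were seen. With those of 9p21, 179 protein-coding genes had no fragment in EV, no count in the depletion libraries and at least 1 FPM in each library labelled KIF20A_OE, and 10 runs of neighbours occurred among them, the longest being the 5 genes of 9p21. HOXC13, HOXC12 and HOXC11, homeobox genes in a row on chromosome 12, were at 19.7 ± 4.29, 2.78 ± 1.88 and 38.1 ± 3.74 FPM (SD, n = 3). The homeobox gene NKX2-2 was at 4.34 ± 0.563 FPM between NKX2-4 at 6.71 ± 3.49 and PAX1 at 5.76 ± 4. The intestinal regulator gene CDX2 was at 38.3 ± 0.498 FPM beside PDX1 at 6.46 ± 1.45, and the kinesin gene KIF26A was at 92.1 ± 1.75 beside TMEM179 at 7.24 ± 2.03.

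Why EV and KIF20A_OE differ in most genes was weighed against the authors' scaling, a raised KIF20A level in the same cells, and another cell type. Scaling is an unlikely source of most calls, since the lower of median-of-ratios scaling and the count test gave 95.9% as many, and these kept 83.5% and 80.7% of the calls by gene and direction, though it may account for part of the rises, of which 75.1% and 71% were kept. A raised KIF20A level could not restore transcripts if the 5 adjacent genes of 9p21 that were silent in EV and expressed in KIF20A_OE were deleted, but DNA was not measured and silencing may be reversed, so this stays open. Cells of the HEK293 embryonic kidney type might fit: of 10 markers written for them, 8 were higher, among them NEFL (80.5 ± 26.5 FPM, no fragment in EV), INA (27.3 ± 13.6, no fragment in EV), PAX2 (9.34 ± 1.73, no fragment in EV) and ZIC2 (158 ± 57.1, 16.5 ± 5.16 in EV), while NR2F1 did not pass. This does not identify the cells, but changes between EV and KIF20A_OE may not be effects of KIF20A.

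The higher PDK4, CPT1A, ANGPTL4 and PLIN2 in SG1 and SG3, none past the edgeR threshold, could reflect a general response of PPAR targets, which govern fatty acid oxidation. SCD was lower, also short of that threshold, and the test of PPAR targets does not address its fall. A separate list of PPAR targets, without the genes of this pattern, scored higher in the depleted libraries by 0.124. Of its 17 tested genes 13 were positive, with an exact permutation p of 0.0119, the smallest of 84 choices, and 0 genes passed on their own. The idea came from top genes of this contrast in the same 9 libraries, so this p is not independent support. The cholesterol list, with a score difference of -0.253, reached the same exact permutation p, and its value adjusted over the lists was 0.345. With the first principal component as a covariate the fold changes of PDK4, CPT1A, ANGPTL4, PLIN2 and SCD kept 97.9% of their size. That component ran from -27.42 to 24.71 in CTRL and from -33.36 to 32.1 in the depleted libraries. It thus varied mostly within the sides compared, so this test cannot decide whether library structure is a source. A difference in medium or density between cultures might act on the same genes and was not tested.

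In splits that ignored the labels of the mean contrast, 36 of 40 gave at least the real 295 genes at an unadjusted p under 0.05, up to 4580 with CTRL replicate 3, SG1 replicate 2 and SG3 replicate 1 as the controls. Lists called reached the real 13 in 11 of 40 splits, with up to 18, so these counts may arise from structure among the libraries. For KIF20A_OE against EV the real split gave 10621 genes and the highest other 0, with 1 of 10 as large, and 20 lists against 20, with 2 of 10. These 10 splits are too few for a share under 0.05.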
